A study of Mus musculus with 2 samples.

How the data were processed

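Single-cell RNA sequencing was used on the colon of wild-type mice and of a transgenic Alzheimer's disease (AD) model, 1 library per genotype. Per the extract protocol in the labels, colon was minced and digested with trypsin and DNase I, red cells were lysed, and 10x libraries were sequenced on a NovaSeq, although the design text names colonic epithelium. Barcodes in the files are 20 bases long, so the kit was not settled. Per the submitters' processing notes, Cell Ranger 3.0.1, STAR and Seurat 3.0.2 were used with the mm10 build. The authors deposited raw UMI counts per gene and barcode, as whole numbers, with no normalization. No barcode in either library held fewer than 500 UMIs, so lower barcodes had been removed before deposit. Other arms named in the series description, such as tuft-deficient animals, organoids and succinic acid treatment, were not analysed here. Both libraries listed the same 33083 genes, of which 31350 (94.76%) had identifiers in the mm10 gene name table used. No gene positions are given, because the other 1733 identifiers were absent from that mm10 annotation and the build behind them was not settled.

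Cells with at least 500 UMIs, at least 200 genes and at most 25% mitochondrial UMIs were kept. Doublets were scored per library with the Scrublet method in scanpy 1.11.5 at an assumed rate of 0.06. It called 4 cells in each library, 0.258% of WT and 0.085% of AD cells, so doublet removal was close to ineffective. Both libraries were clustered together without batch integration, since library and genotype are the same split. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were ranked by dispersion, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) were used. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

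Clusters were named from markers of 24 classes. A cluster took a class when at least 3 markers, and at least 0.3 of the class's markers, were detected in at least 10% of its cells and stood at least 4-fold above the other clusters. Its leading 10 genes had to hold at least as many markers of that class as of any other. Crypt-like and colonocyte-like names were given afterwards among epithelial clusters, at 2-fold. Clusters without another name counted as epithelial-like at 6000 CPM or more of epithelial markers and under 500 CPM of immune markers. T-like clusters were lymphocyte-like clusters with at least 0.8 of the T markers. A cluster with a median depth under the library median divided by 3 needed a marker among its leading 10 genes. The marker lists, 28 gene lists, cell filters, comparisons and 50 alternatives were chosen before the data were examined. The naming thresholds, the joining of T and natural killer markers into 1 lymphocyte-like class and of stem and cycling markers into 1 crypt-like class, and 17 further alternatives were chosen after seeing the data. The ranking of variable genes was replaced after tuft-like counts per library had been seen under the first ranking, and the first ranking is among the alternatives. The crypt marker share was once lowered to 0.25 and then set back to 0.3, with 0.25 kept as an alternative. The thinning generator was changed to a seed per cell. Of 700 list or marker genes, 9 were not matched.

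Shares of cells carry exact Clopper-Pearson intervals and sums of UMIs exact Poisson intervals, all at 95%, and all cover counting error only. Ratios of shares or sums carry exact intervals conditional on the total count. For cell states, each cell was thinned to 1000 UMIs and shallower cells were dropped, and the spread over 20 draws is given. Expression was compared for all epithelial-like cells and for classes with at least 50 cells in each library, so plasma-like cells, with 44 in the WT library, were left out. Tuft-like cells needed 20 in each library, which the 25% limit did not give. They were compared at a limit of 50%, chosen after the counts were seen. UMIs were summed per library and class and given as CPM. For log2 ratios of AD over WT, 0.5 counts were added to each sum. A gene with 0 UMIs in 1 library is given as a bound against a floor of 3 counts over the class in that library. For all epithelial-like cells, the 10 genes with the highest and the 10 with the lowest ratio are named, among genes with at least 200 UMIs and a 2-fold ratio. Within epithelial classes, the rule names 5 each way with at least 100 UMIs (30 for tuft-like), and within other classes 3 each way. Left out of these ranks were markers of other classes, ribosomal protein, mitochondrial, immunoglobulin and T cell receptor, haemoglobin and sex-linked genes, and unnamed gene models. List genes are named beside their list, from the 4 with the largest ratios, and all tuft, amyloid and sex-linked genes may be named. Muc2 and Igha were named after their values were seen, as background. List medians within lymphocyte-like clusters were computed after those of the whole class were seen.

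For each gene list, the median log2 ratio was taken over genes with at least 20 UMIs in both libraries together, with an order-statistic 95% interval. Its percentile was taken among 10000 random lists of the same size, matched within 20 bins of expression, as a description of these libraries. Genes were counted as higher or lower at 1.5-fold. Within classes, lists are described where their percentile was under 1 or over 99, a limit chosen after seeing the data. The ratios and percentiles were tried on simulated Poisson counts drawn from a shared profile over all kept cells. Known folds were given to 200 of the 11307 genes with at least 200 expected UMIs. All 50 genes at each fold of 0.25, 0.5, 2 and 4 came out in the right direction, with median log2 ratios of −2.02, −0.98, 1.00 and 1.97. The largest error was 0.54 in log2, at a fold of 0.25. A raised list of 20 genes stood at percentile 100 and an unchanged one at 50.4. Smaller sums within classes, unequal class composition and UMIs packed in few cells were not simulated, so it does not cover them. Alternatives covered the mitochondrial limit (10%, 50%, none), 1000 UMIs as the minimum depth, doublet removal, clustering resolution (0.5 and 2), each library clustered alone, 4000 variable genes, pseudocount, scaling, class weights, thinning, and list membership limits.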

Results

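The mice compared were wild type (WT) or, per the genotype label, of a transgenic model of Alzheimer's disease (AD). The series asks about tuft cells, rare chemosensory cells of the gut epithelium, in the colon of this model. The 2 libraries compared were, per the labels, 10x single-cell libraries of minced colon, 1 from WT and 1 from AD model mice. With 1 library per genotype no spread between animals was measured and no test between genotypes was possible, so every difference given is a difference between these 2 libraries. The WT library held 4146 barcodes and 26898149 UMIs, and the AD library 6675 barcodes and 38731915 UMIs. After filtering, 1546 WT and 4687 AD cells remained, with median depths of 3714.5 and 3720 UMIs. Parentheses give exact 95% intervals, Clopper-Pearson for shares, Poisson for sums and conditional on the total for ratios. These intervals cover counting error only. Pairs of values are given in the order WT, AD.

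Tuft-like cells made up 2.21% (12 of 542, 1.15 to 3.84) of epithelial-like cells in the WT library and 0.209% (3 of 1437, 0.0431 to 0.609) in the AD library, a ratio of 0.0943 (0.0171 to 0.349). Of all kept cells they were 0.776% and 0.0640%. In epithelial-like cells summed, over 8481687 and 17872123 UMIs, the kinase gene Dclk1 (ENSMUSG00000027797), a common tuft cell marker, had 179 and 50 UMIs, or 21.1 CPM (18.1 to 24.4) in the WT library and 2.80 CPM (2.08 to 3.69) in the AD library. Trpm5 (ENSMUSG00000009246), a cation channel of taste transduction, had 84 and 25 UMIs, and the adaptor gene Sh2d6 had 113 and 24. Chat, which makes acetylcholine, had 22 and 3 UMIs and the taste G protein gene Gnat3 21 and 5. The tuft lineage factor Pou2f3 had 16 and 16 UMIs (1.89 and 0.895 CPM), Kctd12 had 417 and 871 (49.2 and 48.7 CPM), and Il25, the cytokine gene through which tuft cells act on type 2 immunity, had 1 and 1. A total of 60.4% of WT barcodes and 29.2% of AD barcodes exceeded the limit of 25% mitochondrial UMIs. At a limit of 50% the tuft-like shares were 5.76% (121 of 2100, 4.80 to 6.85) and 0.958% (29 of 3026, 0.643 to 1.37), a ratio of 0.166 (0.107 to 0.251). Neither a limit of 10% nor the first ranking of variable genes gave a tuft-like cluster in either library. That ranking was replaced after tuft-like counts had been seen.

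**Figure D1:**
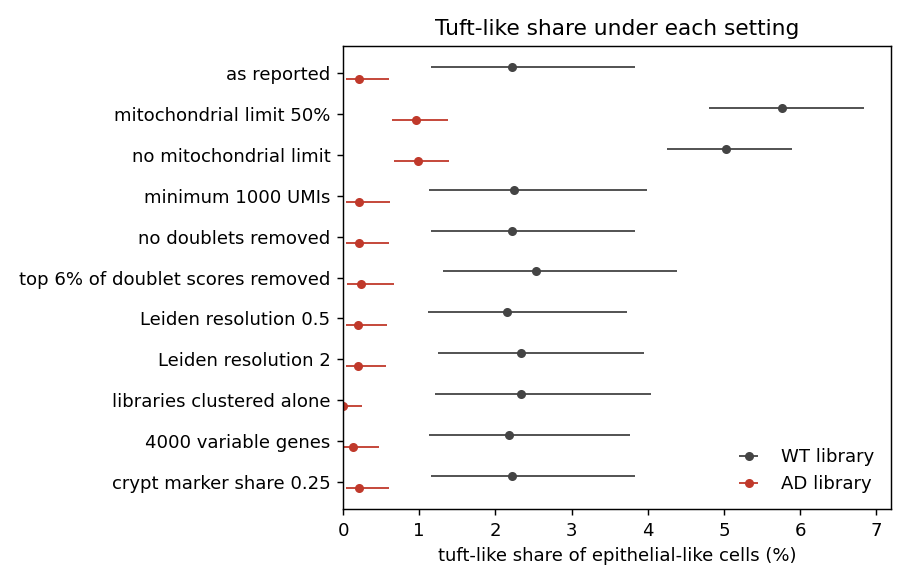
Tuft-like share of epithelial-like cells in percent (x axis) in the WT library (grey) and the AD library (red) under each processing setting that gave a tuft-like cluster, with exact 95% intervals as bars. The AD share lies below the WT share at every setting drawn, from 2.21% and 0.209% as reported to 5.76% and 0.958% with a limit of 50% mitochondrial UMIs, and the AD library clustered alone had no tuft-like cluster.

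Counted by markers within epithelial-like clusters, as cells with at least 3 of the 25 tuft markers after thinning every cell to 1000 UMIs, tuft cells were 2.70% (13 of 481, 1.45 to 4.58) of WT and 0.0741% (1 of 1350, 0.00188 to 0.412) of AD epithelial-like cells. The ratio was 0.0274 (0.000640 to 0.182), and 61 WT and 87 AD cells were too shallow to be thinned. Over 20 thinning draws the counts ran from 11 to 14 WT cells and from 1 to 3 AD cells. The ratio ran from 0.0255 to 0.0891 over these draws, with a median of 0.0548. Fibroblast-like cells, which are not epithelial, passed the same rule in 1 of 199 WT and 1 of 610 AD cells, at median depths of 4390 and 3476 UMIs before thinning. Some of the markers were also found outside epithelial-like cells. Dclk1 had 649 UMIs in all kept AD cells and 50 in epithelial-like ones. B-like cells, which share some of the markers, passed in 5 of 206 and 9 of 411. The AD share of 0.0741%, from 1 cell, was therefore not above the share in fibroblast-like cells at this depth, which is not a clean background. Summed over the 25 markers, tuft marker UMIs were 1.47 per 10000 UMIs (1.39 to 1.55) of epithelial-like cells in the WT library and 0.787 per 10000 UMIs (0.746 to 0.829) in the AD library, a ratio of 0.536 (0.496 to 0.579). Kctd12, with near equal CPM in both, gave 417 of these 1245 WT and 871 of these 1406 AD UMIs. Over all kept cells the values were 3.02 per 10000 UMIs (2.92 to 3.12) and 2.71 per 10000 UMIs (2.65 to 2.77), a ratio of 0.897 that became 1.01 without the markers that immune cells also express. In that reduced sum Kctd12 alone gave 986 of 1696 WT and 3331 of 4435 AD UMIs, so it does not measure tuft cells alone.

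At the limit of 50% mitochondrial UMIs, 121 WT and 29 AD tuft-like cells, 358883 and 53066 UMIs, allowed a comparison within the class that the reported limit did not. Dissociation and immediate early genes, which respond to handling, were higher in the AD cells, with a median log2 ratio of 0.78 (0.14 to 1.02, percentile 100) among 10000 random lists matched on expression. 11 of 18 such genes were at least 1.5-fold higher and 0 lower, among them the transcription factor gene Jun (1.05, 109 and 33 UMIs) and Zfp36 (1.55, 33 and 14 UMIs), which promotes mRNA decay. Antimicrobial genes had a median of −0.64 (−1.67 to 0.80, percentile 0.81), with 3 of 10 genes higher and 6 lower, such as the gasdermin gene Gsdmc2 (−2.07, 99 and 3 UMIs). Mucus genes had a median of 0.61 (percentile 99.06), the tuft gene list one of −0.21 (percentile 14.5), and Trpm5 a log2 ratio of 0.27, 462 and 82 UMIs. The tuft gene list holds the same genes as the markers that named the class. The genes ranked highest in the AD cells were Mptx1 (3.51, 67 and 113 UMIs), an abundant goblet cell pentraxin, Zfp36l1 (1.98, 21 and 12 UMIs), Atp5g2 (1.82, 33 and 17 UMIs), Farp1 (1.81, 39 and 20 UMIs) and Igf2r (1.79, 20 and 10 UMIs). Those ranked lowest had 0 AD UMIs, the kinase gene Hipk2 at least 1.73-fold lower, Sh3glb1 at least 1.63-fold, the interferon regulator Irf7 at least 1.53-fold, and Rreb1 and Limd2 at least 1.48-fold each against a floor of 3 counts.

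Goblet-like cells, which secrete mucus, were 16.8% (91 of 542, 13.7 to 20.2) and 26.2% (376 of 1437, 23.9 to 28.5) of epithelial-like cells, a ratio of 1.56 (1.24 to 1.98) that was 2.28 at a limit of 50% mitochondrial UMIs and 2.51 with none. Crypt-like cells, named by stem and cycling markers, were 36.2% (196 of 542, 32.1 to 40.4) and 24.5% (352 of 1437, 22.3 to 26.8), a ratio of 0.677 (0.567 to 0.811). Hormone-producing enteroendocrine-like cells were 11.3% (61 of 542, 8.72 to 14.2) and 5.22% (75 of 1437, 4.13 to 6.5), a ratio of 0.464 (0.326 to 0.661) that was 0.731 at a limit of 50% mitochondrial UMIs and 0.898 with none. Absorptive colonocyte-like cells were 15.1% (82 of 542, 12.2 to 18.4) and 16.1% (231 of 1437, 14.2 to 18.1), a ratio of 1.06 (0.822 to 1.38). That ratio ran from 0.487 with no mitochondrial limit to 1.44 with no doublets removed. Of the 2 crypt-like clusters, cluster 4 held 111 WT and 308 AD cells, while cluster 16, led by replication-dependent histone genes, held 85 WT and 44 AD cells. Epithelial clusters that reached no class under naming thresholds set after the clusters were seen made up 18.5% (100 of 542, 15.3 to 22.0) and 27.8% (400 of 1437, 25.5 to 30.2). Borders between crypt-like, colonocyte-like and unnamed clusters were unstable: keeping the 8 cells called doublets moved the crypt-like ratio to 0.195 and the colonocyte-like ratio to 1.44.

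Plasma-like cells, which secrete antibody, made up 2.85% (44 of 1546, 2.08 to 3.80) in the WT library and 16.5% (772 of 4687, 15.4 to 17.6) in the AD library, a ratio of 5.79 (4.27 to 8.03). Cluster 0 held most of them in both libraries, 42 WT and 715 AD cells. Enteric glia-like cells were 2.33% (36 of 1546, 1.64 to 3.21) and 0.0640% (3 of 4687, 0.0132 to 0.187), a ratio of 0.0275 (0.00542 to 0.0870). Endothelial-like cells were 6.47% (100 of 1546, 5.29 to 7.81) and 2.07% (97 of 4687, 1.68 to 2.52), a ratio of 0.320 (0.239 to 0.427), or 0.196 at resolution 2 and 0.473 with no mitochondrial limit. They include 1 WT and 13 AD cells of cluster 26 that joined an epithelial cluster at a limit of 50% mitochondrial UMIs. B-like cells were 14.7% (227 of 1546, 13.0 to 16.5) and 10.2% (480 of 4687, 9.39 to 11.1), a ratio of 0.697 (0.594 to 0.820). Lymphocyte-like cells, a class of T, natural killer and innate lymphoid clusters, were 15.7% (243 of 1546, 13.9 to 17.6) and 10.5% (492 of 4687, 9.63 to 11.4), a ratio of 0.668 (0.572 to 0.782). Fibroblast-like cells were 13.9% (215 of 1546, 12.2 to 15.7) and 14.2% (666 of 4687, 13.2 to 15.2). Macrophage and monocyte-like cells were 2.01% (31 of 1546, 1.37 to 2.83) and 2.92% (137 of 4687, 2.46 to 3.45), a ratio of 1.46 (0.981 to 2.23). All epithelial-like cells together were 35.1% (542 of 1546, 32.7 to 37.5) and 30.7% (1437 of 4687, 29.3 to 32.0), a ratio of 0.875 (0.792 to 0.967). Clusters with no class were 3.04% (47 of 1546, 2.24 to 4.02) and 10.3% (483 of 4687, 9.45 to 11.2), and the largest of them, with 20 WT and 301 AD cells, was led by colipase, elastase 1 and immunoglobulin A transcripts. Of the 843 colipase and elastase 1 UMIs in AD cells with no class, 714 lay in 13 cells. With no mitochondrial limit the ratios were 1.15 for B-like and 1.10 for lymphocyte-like cells, and at a limit of 10% that of epithelial-like cells was 1.25, so these 3 directions depended on that limit. Without a limit the fibroblast-like ratio was 1.99 and the plasma-like ratio 9.82.

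**Figure D2:**
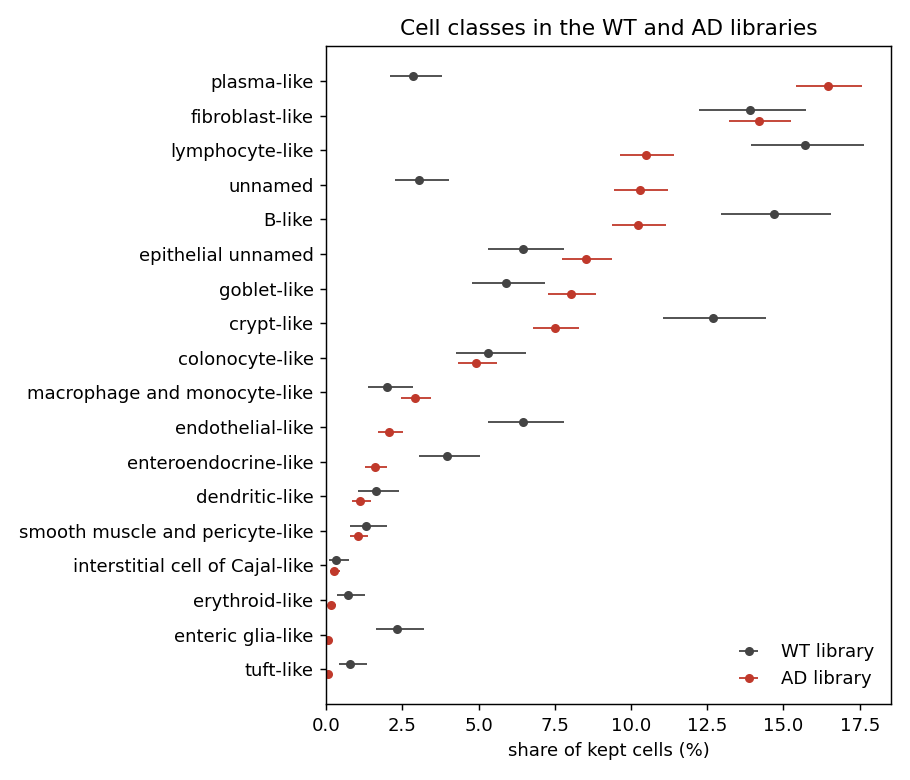
Share of kept cells in percent (x axis) for each cell class in the WT library (grey, 1546 cells) and the AD library (red, 4687 cells), with exact 95% intervals as bars. Plasma-like cells stand at 2.85% and 16.5%, and enteric glia-like cells at 2.33% and 0.0640%.

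T-like cells fell in clusters 5 and 14. In cluster 5, with cells thinned to 1000 UMIs, the coreceptor gene Cd8a was detected in 15.6% (23 of 147, 10.2 to 22.5) of WT and 4.96% (6 of 121, 1.84 to 10.5) of AD cells. Over 20 draws it was found in 17 to 32 WT cells and 3 to 13 AD cells. Tbx21, the regulator of type 1 helper and cytotoxic cells, was detected there in 20.4% (30 of 147, 14.2 to 27.8) and 12.4% (15 of 121, 7.11 to 19.6). In cluster 14, Foxp3, the regulator of regulatory T cells, was detected in 16.0% (4 of 25, 4.54 to 36.1) and 15.7% (20 of 127, 9.89 to 23.3). Cd4 was detected in 8.0% (2 of 25, 0.984 to 26.0) and 18.9% (24 of 127, 12.5 to 26.8), with 1 to 6 WT cells and 18 to 27 AD cells over the draws. Over the 20 draws its median shares were 16.0% and 16.9%. The Cd4 ratio in this cluster ran from 0.656 to 4.13 with a median of 1.00, so no difference was settled. Gata3 stood at 32.0% (8 of 25, 14.9 to 53.5) and 33.1% (42 of 127, 25 to 42.0) in cluster 14. Il17a stood at 0% (0 of 25, 0 to 13.7) and 3.15% (4 of 127, 0.865 to 7.87). Cluster 14 held 25 of the 186 WT and 135 of the 298 AD cells of the 2 clusters, so shares over both clusters depend on that split as well. Over both, Cd4 was detected in 1.16% (2 of 172, 0.141 to 4.14) and 10.1% (25 of 248, 6.63 to 14.5) of thinned cells and 4.30% (8 of 186, 1.87 to 8.30) and 15.1% (45 of 298, 11.2 to 19.7) of unthinned ones. Cd8a was detected in 13.4% (23 of 172, 8.67 to 19.4) and 2.82% (7 of 248, 1.14 to 5.73) thinned, and 28.5% (53 of 186, 22.1 to 35.6) and 6.38% (19 of 298, 3.88 to 9.78) unthinned. Foxp3 was detected in 2.91% (5 of 172, 0.950 to 6.65) and 8.47% (21 of 248, 5.32 to 12.7) thinned, and 5.38% (10 of 186, 2.61 to 9.66) and 11.7% (35 of 298, 8.32 to 16.0) unthinned. Over the draws the AD over WT ratio ran from 2.43 to 15.3 for Cd4, 0.132 to 0.462 for Cd8a and 2.08 to 4.85 for Foxp3. Median ratios over both clusters were 3.58, 0.263 and 2.68. Thinning dropped 14 WT and 50 AD cells. Thinned goblet-like cells, which should lack these 3 genes, had them in 0 of 88 WT and 0 of 372 AD cells, which allows shares of up to 4.11% and 0.987%, at median depths of 19083 and 12421 UMIs against 3100 and 2194.5 in the T-like cells. Cd8a and Foxp3 are among the leading genes of clusters 5 and 14.

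Across lymphocyte-like cells, granzyme A (Gzma), a cytotoxic granule protease, had 500 and 58 UMIs, a log2 ratio of −3.61 (−4.03 to −3.22). Cd8a (−2.43, 134 and 35 UMIs) and granzyme B (−2.23, 436 and 132 UMIs) were the next lowest in the AD library. The highest were the centriole assembly gene Sass6 (5.09, 3 and 169 UMIs), Mptx1 (4.32, 61 and 1743 UMIs) and Calca (3.72, 7 and 140 UMIs), which encodes calcitonin gene-related peptide and is a leading gene of cluster 20. The CD4 helper and regulatory list had a median log2 ratio of 1.11 (0.53 to 1.62, percentile 100), with 13 of 18 genes at least 1.5-fold higher in the AD library. Among them were the cytokine genes Il17a (3.27, 47 and 653 UMIs) and Il17f (3.83, 2 and 50 UMIs) and the costimulatory receptor gene Tnfrsf4 (2.65, 16 and 147 UMIs). The cytotoxic list had a median of −1.11 (−2.43 to 0.31, percentile 0), with 8 of 11 genes lower, such as the chemokine gene Ccl5 (−1.95, 3469 and 1273 UMIs). The succinate and type 2 cytokine list had a median of 1.00 (percentile 99.95), with Il13 at 1.84, 9 and 48 UMIs. The class was split unequally, since cluster 5 gave 161 of 243 WT but 163 of 492 AD cells, and cluster 20, with Il5, Il13, Il17a and Il17f among its leading genes, 6 WT and 56 AD cells. Within clusters 5, 11, 14 and 20 the CD4 list median was 0.08 (−0.92 to 2.33), 0.18 (−0.41 to 0.43), −0.07 (−0.55 to 3.92) and 0.30 (−0.36 to 3.14). These rest on 8, 10, 11 and 9 genes, and all but that of cluster 11 have wide intervals, so differences within clusters were not settled. The cytotoxic median was −0.53 (−3.78 to −0.25, percentile 0.23) in cluster 5, −0.36 in cluster 11 and −0.17 in cluster 14. The succinate list, with 3 genes measured per cluster, stood at −0.07 in cluster 5, 0.90 in cluster 11 and 0.03 in cluster 20. Haemoglobin genes had a median of 3.94 (percentile 100), from 2896 UMIs in 60 AD cells.

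In all epithelial-like cells, Reg3b (ENSMUSG00000071356) and Reg3g (ENSMUSG00000030017), which encode bactericidal lectins, were the lowest in the AD library. Reg3b stood at 160.5 CPM (152 to 169) in the WT library and 0.0560 CPM (0.00142 to 0.312) in the AD library, from 1361 and 1 UMIs. Reg3g stood at 50.0 CPM (45.3 to 55.0) in the WT library and 0.336 CPM (0.123 to 0.731) in the AD library, from 424 and 6 UMIs. Few cells carried Reg3b, since 10 WT colonocyte-like cells had any and 5 of them held 96.7% of the WT UMIs in that class. The secretin gene Sct (log2 −3.32, interval −3.57 to −3.08, 797 and 168 UMIs), Dclk1 (−2.90) and Tph1, which makes serotonin (−2.61, interval −2.78 to −2.45, 1179 and 407 UMIs), followed. These sums also carry class composition, as enteroendocrine-like cells were 11.3% and 5.22% of epithelial-like cells. They held 739 of the WT and 90 of the AD Sct UMIs. Within them Sct stood at −3.22, and Tph1 fell less than over all epithelial-like cells. Next were the exocytosis gene Rims2 (−2.47, 327 and 124 UMIs), the histone gene H2ac8 (−2.46, 158 and 60 UMIs) and the secreted peptide gene Tafa1 (−2.37, 372 and 151 UMIs). The transfer RNA modifier Cdk5rap1 (−2.23, 255 and 114 UMIs) and the growth factor gene Nrg1 (ENSMUSG00000062991, −2.22, 430 and 194 UMIs) closed this group. Highest were Ly6c2 (log2 4.67, interval 3.77 to 5.98, 8 and 457 UMIs), a leading gene of plasma-like cluster 0, and Sass6 (ENSMUSG00000027959), at 5.66 CPM (4.17 to 7.50) in the WT library and 47.3 CPM (44.1 to 50.6) in the AD library. The lipase gene Pnliprp2 (2.48, 74 and 875 UMIs), the calmodulin kinase gene Camk2b (2.38, 138 and 1517 UMIs), the lymphocyte activation gene Cd69 (2.26, 20 and 206 UMIs) and the chromatin gene Asxl3 (2.04, 54 and 471 UMIs) came next. They were followed by Mptx1 (1.75, 52818 and 374796 UMIs), the sugar phosphate transporter gene Slc37a2 (1.73, 118 and 826 UMIs), the peptidase gene Trhde (1.72, 39 and 274 UMIs) and the colipase gene Clps (1.71, 427 and 2946 UMIs). The median gene had a log2 ratio of −0.05. With WT class shares as weights in both libraries, 7 of the genes named here moved outside their intervals, 13 stayed inside and 0 reversed.

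Over all epithelial-like cells summed, proliferation genes were lower in the AD library, with a cell cycle list median of −1.36 (−1.80 to −0.97, percentile 0) and 15 of 16 genes at least 1.5-fold lower. By class the median was −1.30 in goblet-like, −1.29 in crypt-like and −0.47 in enteroendocrine-like cells. In colonocyte-like cells it was 0.40, with 3 of 7 genes higher and 0 lower. The sum also carries composition, as the histone-led cluster 16 gave 85 of 542 WT and 44 of 1437 AD cells. The centromere histone gene Cenpa (−1.87, 423 and 244 UMIs) and Top2a (−1.86, 657 and 381 UMIs), which untangles replicated DNA, were among the lowest. The tuft list median was −1.58 (−2.95 to −0.59, percentile 0), with 14 of 18 genes lower and 0 higher. Antigen presentation genes had an MHC class II median of 0.45 (0.04 to 0.85, percentile 99.82), with 1 of 6 genes at least 1.5-fold higher, the invariant chain gene Cd74 (0.85, 214 and 817 UMIs), and 5 between. MHC class I had a median of −0.04 (percentile 47.6), with 0 genes higher and 1 lower. RNA of immune cells was not separated from these values. Cholesterol synthesis had a median of 0.27 (percentile 99.78), led by the pathway gene Hmgcs1 (0.79, 1026 and 3733 UMIs). Ion and water transport had a median of 0.23 (percentile 99.44), led by the anion channel gene Best2 (1.46, 47 and 275 UMIs) and the water channel gene Aqp8 (0.72, 246 and 855 UMIs). The NF-kB and inflammatory list had a median of 0.24 (percentile 99.58), with 3 of 19 genes higher, including the chemokine gene Ccl20 (0.68, 298 and 1008 UMIs). Nuclear oxidative phosphorylation genes had a median of −0.16 (percentile 0.02) and mitochondrially encoded genes one of −0.24 (percentile 0.36), with 37 of 38 and 13 of 13 genes between the 1.5-fold limits. The CD4 list, of lymphocyte genes that epithelial cells should lack, had 5 measured genes and a median of 1.96 (percentile 100), such as Ctla4 (2.00, 10 and 88 UMIs), a brake on T cells. The succinate and type 2 list had a median of −0.57 (percentile 1.04), with the succinate-linked channel gene Trpm5 lowest and the goblet cell effector gene Retnlb highest (1.14, 12265 and 56970 UMIs). Tight and adherens junction genes had a median of 0.04 (percentile 58.0), with 21 of 21 between the limits, mucus genes 0.13 (percentile 89.0), hormone genes −0.23 (percentile 3.78) and antimicrobial genes −0.0038 (percentile 46.9). The remaining lists lay between −0.59 and 0.24. The oxidative phosphorylation median was 0.059 after thinning and 0.017 as a mean over cells, and the CD4 median −0.21 after thinning. At a limit of 10% mitochondrial UMIs the succinate median was 0.33 and the mitochondrially encoded one 0.0058.

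**Figure D3:**
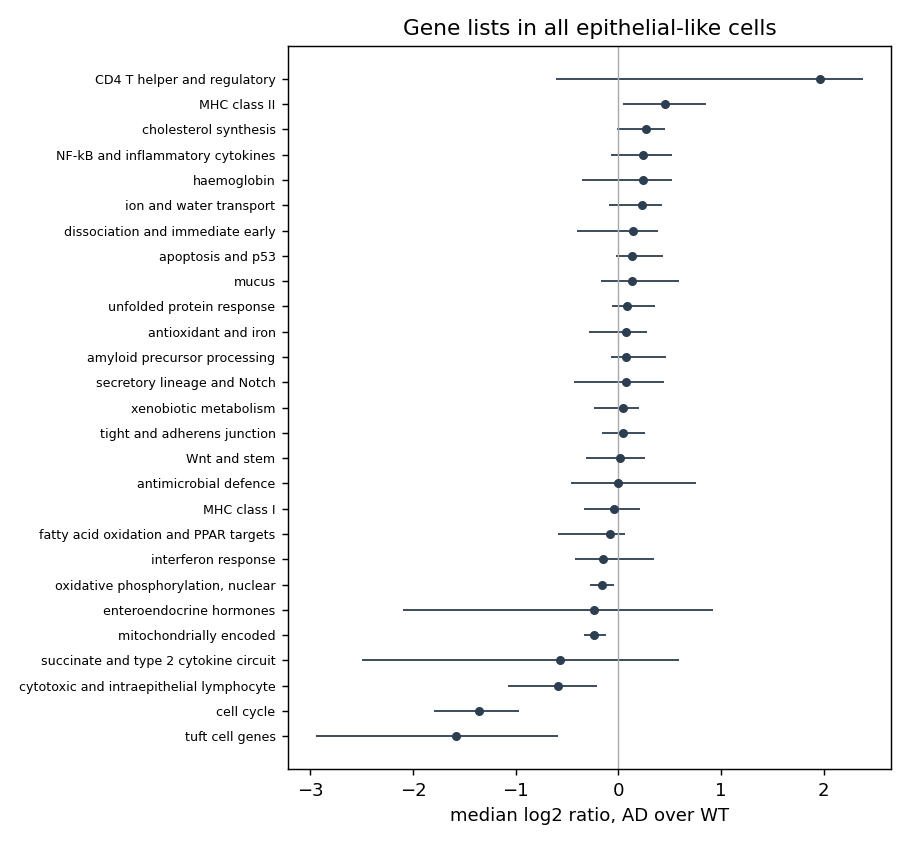
Median log2 ratio AD over WT (x axis) of each gene list in all epithelial-like cells, with bars for the 95% interval of the median over the list's genes. The tuft list lies at −1.58 and the cell cycle list at −1.36, while the junction list lies at 0.04, and the CD4 list, at 1.96 from 5 genes, turned to −0.21 when cells were thinned, as did oxidative phosphorylation, from −0.16 to 0.059.

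App, the amyloid precursor gene, had 1481 and 3652 UMIs in epithelial-like cells, a log2 ratio of 0.23 (0.14 to 0.31). Psen2, a γ-secretase gene, had a log2 ratio of −0.07, 138 and 277 UMIs. Bace1, the β-secretase gene, stood at 0.03, 198 and 427 UMIs, its relative Bace2 at 0.89, interval 0.68 to 1.11, 229 and 894 UMIs, and Thy1, whose promoter is used in many neuronal transgenes, at 0.95, interval −0.27 to 2.61, 6 and 26 UMIs. The amyloid precursor processing list had a median of 0.08 (−0.07 to 0.46, percentile 85.1), with 16 of 19 genes between the 1.5-fold limits. Reads from human transgenes were not separated from reads of the mouse genes.

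Within goblet-like cells, Reg3b had 103 and 0 UMIs, at least 98.7-fold lower in the AD library against a floor of 3 counts, with all 103 UMIs in 3 of 91 WT cells. The mitotic genes Cdc20 (−2.82, 72 and 29 UMIs), Cenpf (−1.88, 96 and 75 UMIs) and Ccna2 (−1.81, 55 and 45 UMIs) and the surface protein gene Ly6a (−1.93, 93 and 70 UMIs) were the next lowest. The cell cycle list had a median of −1.30 (−1.57 to −0.58, percentile 0) with 12 of 16 genes lower. Highest were Camk2b (4.13, interval 3.02 to 5.90, 5 and 276 UMIs) and Sass6 (3.15, 9 and 242 UMIs). Camk2b was most abundant in plasma-like cells, at 1502 and 1120.0 CPM, against 2.65 and 51.0 CPM here, and its source in epithelial classes was not settled. They were followed by the epithelial stress gene Sprr1a (2.25, 22 and 308 UMIs), the secreted nuclease gene Dnase1l3 (2.25, 11 and 157 UMIs) and the monoamine transporter gene Slc29a4 (2.11, 13 and 167 UMIs). Hormone genes had a median of 2.64 (percentile 100), with the proglucagon gene Gcg at 0 and 98 UMIs, at least 11.4-fold higher, and Insl5 at 4.95, 1 and 133 UMIs. These are enteroendocrine transcripts and were not read as goblet expression: 98 Gcg UMIs lay in 9 of 376 AD cells, and over AD B-like, lymphocyte-like and fibroblast-like cells Gcg stood at 3.51 and Insl5 at 5.57 CPM. The NF-kB list had a median of 0.29 (percentile 99.87), with Cxcl16 at 1.02, 16 and 96 UMIs, oxidative phosphorylation one of −0.30 (percentile 0), mitochondrially encoded genes −0.30 (percentile 0.29) and haemoglobin −1.86 (percentile 0.06). Thinning, which left 88000 and 372000 UMIs in the class, gave an NF-kB median of −0.49. That value rests on few UMIs per gene, where the 0.5 counts added to each sum weigh heavily, and settles no direction.

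In colonocyte-like cells Reg3b had 1109 and 0 UMIs and Reg3g 197 and 0 UMIs, at least 926-fold and at least 165-fold lower in the AD library. The WT UMIs lay in 10 and 4 of 82 cells. The interferon-induced gene Ifit1bl1 (−2.69, 78 and 30 UMIs), the heat shock gene Hsph1 (−1.97, 66 and 42 UMIs) and the nutrient-sensing GTPase gene Rragd (−1.83, 64 and 45 UMIs) followed. The antimicrobial list had a median of −0.52 (−0.88 to 0.28, percentile 0) with 7 of 15 genes lower, but of 0.22 at a limit of 10% mitochondrial UMIs. Highest were Ly6c2 (4.74, interval 2.81 to 10.64, 1 and 100 UMIs) and Sass6 (4.60, interval 3.04 to 7.97, 2 and 151 UMIs). Camk2b (3.84, interval 2.48 to 6.35, 3 and 125 UMIs), most abundant in plasma-like cells, Mptx1 (3.58, 64 and 1928 UMIs) and the small GTPase gene Rap2b (1.81, 12 and 109 UMIs, but −0.87 after thinning) were next. Thinning left 68000 and 224000 UMIs in this class, from 1113917 and 2791131. The thinned Rap2b value therefore rests on few UMIs and settles no direction. Cholesterol synthesis had a median of 0.39 (percentile 99.96), with Hmgcs1 at 0.86, 182 and 832 UMIs, and −0.079 after thinning.

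Crypt-like cells had cell cycle genes lower in the AD library, with a median of −1.29 (−1.73 to −0.94, percentile 0) and 16 of 16 genes at least 1.5-fold lower, such as the nucleotide synthesis gene Rrm2 (−2.08, 142 and 46 UMIs). The list holds the same genes as the cycling markers used to name this class. Its median is therefore not independent of which clusters were joined. Reg3g had 154 and 0 UMIs, at least 71.0-fold lower, and Reg3b 106 and 1 UMIs, a log2 ratio of −6.62 (−12.51 to −4.69), in 17 and 18 of 196 WT cells. H2ac8 (−2.72, 107 and 22 UMIs), the mitotic kinase gene Pbk (−2.48, 163 and 40 UMIs) and Cdk5rap1 (−2.33, 114 and 31 UMIs) were next lowest. The histone-led cluster 16 made up 85 of 196 WT and 44 of 352 AD cells of the class. Highest were Camk2b (4.64, interval 3.92 to 5.57, 14 and 498 UMIs), at 4.04 and 104 CPM and most abundant in plasma-like cells, and the cytochrome gene Cyp2c68 (3.45, 29 and 447 UMIs). Asxl3 (2.72, 10 and 95 UMIs, but −0.88 after thinning), Sass6 (2.56, 25 and 207 UMIs) and the Golgi calcium pump gene Atp2c2 (2.22, 14 and 93 UMIs) were next. Thinning left 182000 and 335000 UMIs in this class, from 3463228 and 4791186. The thinned Asxl3 value therefore rests on few UMIs and settles no direction. Higher list medians were those of MHC class II (0.79, percentile 99.69), the succinate and type 2 list (0.82, percentile 99.78, 5 genes measured) and cholesterol synthesis (0.40, percentile 99.83). For MHC class II, RNA of immune cells was not separated, and Igha stood at 152 and 1832 CPM in this class. For the succinate list, which includes the goblet cell gene Retnlb, RNA of goblet cells was not separated, and Muc2 stood at 69.3 and 259 CPM. Others were NF-kB (0.39, percentile 99.63, with Ccl20 at 1.03, 185 and 523 UMIs), dissociation and immediate early genes (0.39, percentile 99.96) and haemoglobin (1.37, percentile 100). At a limit of 50% mitochondrial UMIs the haemoglobin median was −1.78, and at 25% its 246 and 1067 UMIs lay in 129 of 196 WT and 75 of 352 AD cells. Oxidative phosphorylation stood at −0.18 (percentile 0.15).

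In enteroendocrine-like cells the pancreatic polypeptide gene Ppy had 0 and 142 UMIs, at least 41.6-fold higher in the AD library, and the ghrelin gene Ghrl had 3 and 127 UMIs, a log2 ratio of 5.00 (3.64 to 7.52). Secretin was lowest (Sct, −3.22, interval −3.56 to −2.91, 739 and 90 UMIs), and Tph1 stood at −1.79, 1167 and 384 UMIs, while the colonic hormone gene Insl5 stood at 1.78, 2257 and 8840 UMIs. The hormone list as a whole had a median of 0.44 (−1.22 to 1.69, percentile 99.8), with 6 of 12 genes higher and 5 lower. The ion channel gene Asic2 (−3.08, 152 and 20 UMIs), the small heat shock gene Hspb1 (−2.71, 100 and 17 UMIs), Auts2 (−2.07, 101 and 27 UMIs) and Smad7 (−2.04, 81 and 22 UMIs) were also low. High were Mptx1 (6.87, 59 and 7889 UMIs), Sval1 (3.64, 7 and 106 UMIs) and the kallikrein gene Klk1 (1.89, 46 and 195 UMIs). The unfolded protein response list had a median of 0.56 (percentile 100), with the disulfide isomerase gene Pdia6 at 1.45, 41 and 128 UMIs. The secretory lineage list had one of 0.51 (percentile 99.36), with Spdef, a goblet lineage factor, at 3.60, 2 and 34 UMIs. Goblet genes were also high in this class, Mptx1 at 102 and 11995 CPM and Muc2 at 98.5 and 2827 CPM, so these values were not told apart from RNA of goblet cells or mixed barcodes. Oxidative phosphorylation had a median of −0.24 (percentile 0.01), or 0.084 as a mean over cells, and mitochondrially encoded genes −0.33 (percentile 0.5). Cluster 27, with Ppy and Insl5 among its leading genes, held 8 of the 61 WT and 18 of the 75 AD cells. Sval1 turned to −0.50 at a limit of 10% mitochondrial UMIs.

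Among B-like cells Sass6 was highest in the AD library (6.11, interval 4.20 to 12.01, 1 and 186 UMIs), then the Integrator gene Ints14 (2.72, 9 and 112 UMIs) and Mptx1 (2.39, 70 and 662 UMIs). The cannabinoid receptor gene Cnr2 (−1.46, 71 and 46 UMIs), the chaperone gene Dnajc1 (−1.46, 77 and 50 UMIs) and the peptide transporter gene Slc15a2 (−1.45, 108 and 71 UMIs) were lowest. The cell cycle list had a median of 0.87 (percentile 99.98), with Rrm2 at 1.77, 4 and 27 UMIs, and −0.071 as a mean over cells. In fibroblast-like cells Mptx1 (4.0, 63 and 2791 UMIs), Sass6 (3.79, 7 and 285 UMIs) and Camk2b (3.12, 4 and 107 UMIs) were highest. The matrix protease gene Mmp16 (−1.57, 106 and 98 UMIs), the growth factor gene Hgf (−1.40, 93 and 97 UMIs) and the translation factor gene Eif2b3 (−1.33, 53 and 58 UMIs) were lowest. Fibroblast-like list medians were 0.32 (percentile 100) for the unfolded protein response, 0.29 (percentile 99.51) for NF-kB, with the NF-kB inhibitor gene Tnfaip3 at 1.58, 12 and 102 UMIs, and −0.21 (percentile 0) for oxidative phosphorylation. The unfolded protein response value was not told apart from plasma cell RNA, as Igha stood at 154 and 6055 CPM in this class. In endothelial-like cells Mptx1 (3.14, 21 and 164 UMIs) and the metallothionein gene Mt1 (2.51, 35 and 175 UMIs) were higher in the AD library. The osteopontin gene Spp1 ranked first, with 0 and 570 UMIs, at least 219-fold higher, but was not read as endothelial. All 570 UMIs lay in the 13 AD cells of cluster 26 that joined an epithelial cluster. The lymphatic genes Reln (−2.08, 148 and 30 UMIs) and Flt4 (−1.61, 93 and 26 UMIs) and the water channel gene Aqp1 (−1.62, 268 and 75 UMIs) were lowest. Reln follows cluster 26, which held 147 of its 148 WT and all 30 AD UMIs, and of which 12 WT and 7 AD cells stayed endothelial-like at the 50% limit. Endothelial-like list medians were 0.56 (percentile 100) for dissociation and immediate early genes, with Klf6 at 1.68, 69 and 192 UMIs, and 0.44 (percentile 99.85) for the unfolded protein response, which was not told apart from plasma cell RNA (Igha at 265 and 12710 CPM) or from the 13 AD cells above. They were 1.98 (percentile 99.96) for 4 Wnt and stem genes, with 26 of the 30 AD UMIs of Sox9 in those 13 cells, and 0.33 (percentile 99.96) for mitochondrially encoded genes, the last turning to −0.54 at a limit of 50%. The values of Mt1 and of the dissociation list were not told apart from those 13 AD cells either.

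Some transcripts of other cell types were higher in AD classes that should lack them. In B-like, lymphocyte-like and fibroblast-like cells together, immunoglobulin A heavy chain (Igha) stood at 264 and 6769 CPM, Mptx1 at 82.5 and 1072 CPM, and the mucin gene Muc2 at 83.4 and 459 CPM. Values of Mptx1, mucus and MHC class II genes outside their usual cell types were not read as expression, and in AD enteroendocrine-like cells Mptx1 and Muc2 lay above this background. Such mucus medians were 0.64 (percentile 100) in colonocyte-like, 0.63 (percentile 100) in crypt-like, 2.93 (percentile 100) in enteroendocrine-like, 1.44 (percentile 100) in lymphocyte-like, 1.05 (percentile 100) in B-like, 2.54 (percentile 100) in fibroblast-like and 1.31 (percentile 100) in endothelial-like cells. MHC class II medians were 1.01 (percentile 99.77) in lymphocyte-like and 2.00 (percentile 100) in fibroblast-like cells, and antimicrobial medians 0.90 (percentile 99.99), 0.58 (percentile 99.98) and 0.67 (percentile 99.67) in B-like, fibroblast-like and endothelial-like cells. The antimicrobial median turned to −0.12 in B-like and −0.53 in endothelial-like cells at a limit of 50% mitochondrial UMIs. Haemoglobin stood at 12959 and 1801 CPM over all barcodes, but at 172 and 631 CPM in those 3 classes together, where 2896 of 3058 AD UMIs lay in lymphocyte-like cells. Its medians were −1.50 (percentile 0.03) in B-like and −2.40 (percentile 0) in fibroblast-like cells, the last 0.62 at a limit of 50%.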

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

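The tests with no mitochondrial limit and of the unnamed cells were chosen after the results they measure were seen. Values here come mostly from cells or genes outside the comparisons of cell classes and gene expression.

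Barcodes above 25% mitochondrial UMIs were left out of the values reported at that limit, and at a limit of 50% they held 107 of the 121 WT and 26 of the 29 AD tuft-like cells. A limit that removed tuft-like cells unequally could give a lower AD share, but with no limit the AD over WT ratio of tuft-like shares stayed at 0.196 (0.129 to 0.289), from 143 of 2844 and 32 of 3247 epithelial-like cells. Clustering or depth could do the same, but among all deposited barcodes with epithelial markers, thinned to 1000 UMIs and counted by 3 tuft markers without clusters, the ratio was 0.109 (0.0383 to 0.251), from 58 of 2174 and 6 of 2069, and 0.0906 to 0.156 over 20 draws. It covers barcodes of at least 1000 UMIs, and 368 WT and 648 AD barcodes below that depth were not counted. Before thinning, these barcodes needed at least 3 epithelial marker UMIs, 6000 CPM of such markers outside mitochondrial genes and at most 1 immune marker UMI. Tuft-like cells carried some immune marker RNA, so this gate can drop them, more so at greater depth. In epithelial-like clusters with no mitochondrial limit, the same thinned rule found 127 of 2391 WT and 20 of 2376 AD cells. The first value argues against the mitochondrial limit as the whole cause, and the second against clustering, for the barcodes that passed the gate. Depth is not decided, because the gate used unthinned counts. Genotype, the stretch of colon taken and losses during dissociation stay open as well, and genotype was not tested, since 1 library each ties them together.

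Transcripts of 17 pancreatic acinar genes, a list not used in the comparisons, stood at 94.1 CPM (91.1 to 97.2) over all AD barcodes and at 5.09 (4.28 to 6.02) over all WT barcodes. For the low level in most AD classes, free RNA was not decided. The median of B-like, lymphocyte-like and fibroblast-like cells was 1.35 times the goblet-like value of 15.3 CPM, inside the 3-fold limit set beforehand. Median AD depths were 1960, 2083 and 3476.5 UMIs in those 3 classes and 12149 in goblet-like cells. Similar CPM is therefore not a similar number of UMIs per barcode, and this test cannot decide. In WT goblet-like cells the value was 15.4 CPM. Free RNA is argued against for the unnamed AD cells, which stood 144 times (118 to 178) above those 3 classes together. They held 3124 of the 3479 UMIs in kept AD cells, in 40 of 483 cells. Of these, 3095 UMIs lay in 13 cells that at a limit of 50% mitochondrial UMIs joined a cluster of 0 WT and 21 AD cells led by Cpa1 and Ctrb1, which are acinar cell genes. In goblet-like cells an acinar source is argued against for colipase and elastase 1, because their ratio to the acinar list was 40.1 times (28.2 to 56.9, from a normal approximation on the log scale) higher in AD goblet-like cells than in those 3 classes. In the unnamed AD cells it is not, since 714 of their 843 UMIs for these 2 genes lay in the same 13 cells. No biological explanation was tested.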

How the results depend on the processing

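Tests with no mitochondrial limit, with the top 6% of doublet scores removed, with the first ranking of variable genes, with a crypt marker share of 0.25, with the 50% limit for expression and with 20 thinning draws were chosen after the results were seen. The alternatives gave 156 values of 17 shares and counts, of which 119 lay inside the interval of the reported value, 32 outside it and 5 were reversed. Of 598 values of 84 named genes, 426 lay inside, 169 outside and 3 were reversed. Of 663 values of 74 list medians these numbers were 603, 43 and 17. Reversals were counted for shares, counts and genes whose interval left out no difference and for lists outside the central 95% of random lists, so values outside an interval can lie on the other side of 1, as some colonocyte-like ratios do. The tuft-like share of epithelial-like cells was lower in the AD library at each setting that gave one, with ratios from 0.0602 to 0.196 in clusters. No tuft-like cluster came with the 10% limit or the first ranking, and clustered alone the AD library had 0 tuft-like of 1512 epithelial-like cells (upper limit 0.244%). Crypt-like cells gave no ratio at the 10% limit or with each library clustered alone, nor macrophage and monocyte-like cells in the latter. For shares, AD over WT ratios are given. At a 10% mitochondrial limit, the ratio was 0.573 for B-like, 0.551 for lymphocyte-like, 0.785 for colonocyte-like and 0.314 for enteroendocrine-like cells, and reversed to 1.25 for epithelial-like cells. At 50% it was 0.981 for B-like, 1.73 for fibroblast-like, 0.936 for lymphocyte-like, 8.87 for plasma-like, 0.737 for epithelial-like, 0.602 for colonocyte-like, 0.362 for crypt-like, 0.731 for enteroendocrine-like and 2.28 for goblet-like cells. With no limit it reversed for B-like (1.15) and lymphocyte-like cells (1.10), and was 0.473 for endothelial-like, 1.99 for fibroblast-like, 9.82 for plasma-like, 0.696 for epithelial-like, 0.487 for colonocyte-like, 0.545 for crypt-like, 0.898 for enteroendocrine-like and 2.51 for goblet-like cells. A minimum of 1000 UMIs gave 0.986 for epithelial-like and 1.43 for colonocyte-like cells. Without doublet removal colonocyte-like stood at 1.44 and crypt-like at 0.195, and with the top 6% of scores removed colonocyte-like at 1.40. Crypt-like cells stood at 0.189 at resolution 0.5 and 0.190 with 4000 variable genes, epithelial-like at 0.970 when clustered alone, and endothelial-like at 0.196 at resolution 2. There the Foxp3 ratio reversed to 0.992, because only the Foxp3 cluster then counted as T-like. Tuft marker UMIs stood at 0.596 in epithelial-like cells and 0.790 in all cells over all deposited barcodes. They reversed to 1.01 in all kept cells without immune-shared markers, where most UMIs were of Kctd12. Reversed log2 ratios were these. At 10%: Sval1 in enteroendocrine-like cells −0.50, the succinate list 0.33 and mitochondrially encoded genes 0.0058 in all epithelial-like cells, and antimicrobial genes in colonocyte-like cells 0.22. At 50%: haemoglobin in crypt-like (−1.78) and fibroblast-like cells (0.62), antimicrobial genes in B-like (−0.12) and endothelial-like cells (−0.53), and mitochondrially encoded genes in endothelial-like cells (−0.54). Thinned: Rap2b in colonocyte-like −0.87 and Asxl3 in crypt-like cells −0.88, oxidative phosphorylation 0.059 and the CD4 list −0.21 in all epithelial-like cells, NF-kB in goblet-like −0.49 and cholesterol synthesis in colonocyte-like cells −0.079. For genes with few UMIs, and for lists of such genes like NF-kB in goblet-like cells, the thinned values settle no direction. Thinning left, for example, 68000 WT and 224000 AD UMIs in colonocyte-like cells. As means over cells: oxidative phosphorylation in all epithelial-like 0.017 and enteroendocrine-like 0.084 and cell cycle in B-like cells −0.071. With list genes from 1 UMI, antimicrobial genes in B-like cells stood at −0.059, and without doublet removal haemoglobin in fibroblast-like cells at 0.65. For all but Foxp3 the cause was not tested.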

Other observations

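The tests here were written before their results were seen, except the interval used to read the median of leading genes and the median without haemoglobin, which were chosen after the first median was seen.

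At a limit of 50% mitochondrial UMIs, a colonocyte-like cluster held 317 WT and 11 AD cells, 10 of which were WT colonocyte-like cells at the 25% limit. The 2 suspensions may come from different stretches of the colon: posterior Hox genes and Prac1 in crypt-like, goblet-like and colonocyte-like cells together had 1286 WT and 3803 AD UMIs, a CPM ratio of 1.47 (1.38 to 1.57). The ratio was 1.14 (1.01 to 1.29) in goblet-like, 1.26 (1.09 to 1.45) in colonocyte-like and 1.97 (1.80 to 2.15) in crypt-like cells, which neither reached 2-fold in all 3 classes nor stayed within 1.5-fold, so region and genotype cannot be told apart. Damage could also have set these cells apart: of 18 measured leading genes of the cluster, 10 were higher in WT colonocyte-like cells at the 25% limit, with a median log2 ratio of −0.15 (−0.96 to 0.63), an interval too wide to decide. Without 3 haemoglobin genes, 10 of 15 were higher in WT cells, with a median of −0.48 (−1.08 to 0.63), which leaves this open too. Genotype stays open as well, untested.

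Sass6 UMIs numbered 67 in kept WT and 2213 in kept AD cells, 5.42 and 69.3 CPM, a ratio of 12.8 (10.0 to 16.5). It was higher in the AD library in each class tabulated, from a ratio of 3.96 in enteroendocrine-like to 104 in B-like cells, with 0 WT and 172 AD UMIs in unnamed cells. Haemoglobin UMIs numbered 348568 and 69747 over all barcodes. Xist had 0 UMIs over all barcodes of both libraries, as had Eif2s3y, while Ddx3y had 10 and 11, Uty 1 and 10, and Kdm5d 0 and 5. Since any mouse expresses Xist or the Y-linked genes, these zeros were not taken as measurements, and the sex of the animals could not be read from them.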
